A study of Mus musculus with 34 samples.

How the data were processed

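RNA of mouse cells was sequenced in 34 libraries. The labels name 9 groups: stem cells of the CBMS1 line at day 0, epiblast-like cells at day 2, embryoid bodies at days 3, 4, 5, 6 and 7, epiblast stem cells (EpiSC) and embryonic fibroblasts (MEF). Per the labels' protocols, libraries were made from total RNA with a stranded kit that selects messenger RNA. The groups were taken from the titles and source names. In 9 of the 25 libraries of the course the cell type field of the labels names another stage than the title and source name, which were followed. The fibroblasts come from 2 cultures, each sampled at 3 passages, and the labels give a project number by which the libraries were divided into project A (19 libraries) and project B (15 libraries).

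The deposited table held FPKM per gene and library, made by the authors with cutadapt 1.4.1, HISAT2 2.0.4, Cuffdiff and Cufflinks 2.2.1 on mouse build mm9, per the submitters' processing notes. Settings, filters and the scaling between libraries were not stated. It held 24103 entries, of which 1044 lay on chromosome X, 14 on chromosome Y and 129 on unplaced sequence. Of the symbols, 184 occurred in more than 1 entry, and 664 entries named more than 1 symbol, so that values of overlapping genes and close copies are uncertain. Whether the strand was used in counting was not stated, so that reads of antisense pairs such as Xist and Tsix cannot be assigned with certainty. Start positions are printed as deposited. No pair of libraries was identical.

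Reads were not analysed, and fragment totals, depth and its counting error were not known. FPKM of genes with few fragments lie on steps whose size falls with depth. Relative depth was estimated from these steps in values up to 0.15 FPKM, where between 54.8% and 87.9% of the ratios to a reference library lay in step, within 0.04 on the log2 scale. It ran from 0.85 to 1.18 times the median library. Transcript lengths for a check of 1 library came from a reference annotation, joined by RefSeq identifier.

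The comparisons, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes with at least 1 FPKM in at least 3 libraries were kept, 14595 in all. A pseudocount of 1 FPKM was added before taking log2. All groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend in the variance). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with a difference of at least 1 on the log2 scale. The 12 comparisons were day 2 with day 0, day 7 with days 2 and 0, EpiSC with days 2 and 7, MEF with days 7 and 0, and each of the 5 steps of 1 day from day 2 to day 7. A moderated F test over days 0 to 7 asked for any change, with a range of group means of at least 1. All p-values of single genes printed in the report are from these limma fits.

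Across genes, 30 lists of cell type markers and pathways were tested per comparison with camera of limma, with a preset correlation between genes of 0.01, and again with an estimated correlation. Adjustment was over the 30 lists of a comparison. List members were counted as risen or fallen by the calls over all genes, and also with p-values adjusted over the members alone. Expression on chromosome X was compared as the ratio of the median FPKM of X-linked to autosomal genes per library, and groups were compared by exact two-sided permutation. The day nearest to EpiSC was found by 1 minus Pearson r.

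The genes named were the 8 largest rises and the 8 largest falls (3 and 3 for steps of 1 day) among called genes whose libraries did not overlap and whose higher mean was at least 10 FPKM. Up to 4 members of each list with the smallest adjusted p were added. Xist, Tsix, Pou5f1, Nanog, Sox2, Zfp42, Fgf5, Otx2, Sox1, Pax6, T, Sox17, Col1a2, Rif1 and Ctcf could be named in any comparison. Some genes the rule names are not reported here. Genes named outside this rule were chosen after their values were seen, and the text says so.

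The alternatives tried were another pseudocount, other filters and no filter, quantile normalization, rescaling by median ratios, fits of 2 groups only, the project as a covariate, each project alone, no minimum difference, each library left out in turn, blocks by replicate number and by culture course, and means per MEF culture. For lists they were an estimated correlation and the fry test. Added after the data were seen were fits without loci under 200 bases, EpiSC values less a fibroblast share, fits without genes 10 times higher in MEF than at any day (both also for the day nearest to EpiSC), the X to autosome ratio with means per MEF culture, and the block for lists. For each comparison the libraries were also split in other ways, up to 100 splits, and the calls counted, for MEF also with the mean per culture as 1 sample.

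The fits were tested on simulated data. Of 100 genes given a 4-fold change, 100 were called between days 2 and 7 and 99 between days 3 and 4. Of 100 given a 2-fold change, 98 and 86 had an adjusted p under 0.05, and 32 and 35 also passed the minimum difference. In the same data 0 and 1 unchanged genes were called. Of 100 random lists, 1 had an unadjusted camera p under 0.05 in each comparison. The simulated genes varied independently, so correlation within a list was not tested. Halving all X-linked values gave 0.5 of the original ratio, by arithmetic. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Splicing, isoforms and replication timing were not analysed here.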

Results

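RNA sequencing was done on 34 libraries of mouse cells in 9 groups. Cells of the female embryonic stem cell line CBMS1 (ESC day 0, n = 3 libraries) were turned into epiblast-like cells (EpiLC day 2, n = 5) and then grown as aggregates, called embryoid bodies (EB days 3, 4, 5 and 6, n = 3 each, and EB day 7, n = 5). No factors were added, a regime that leads towards neurectoderm. Epiblast stem cells grown on fibroblasts with Activin and FGF (EpiSC, n = 3) and embryonic fibroblasts of 2 cultures over 3 passages (MEF, n = 6) complete the set. The deposited values were FPKM per gene, fragments scaled by transcript length, and how libraries were scaled to each other was not stated. Depth was unknown, but relative depth, estimated from FPKM steps, ran from 0.85 to 1.18 times the median library. Between 11303 and 12212 genes per library reached 1 FPKM. Libraries of a group correlated at Pearson r of 0.96 to 0.99 across genes. The labels name 2 sequencing projects, A (19 libraries) and B (15 libraries). The labels call the replicates biological but did not tell whether each was a separate culture, so the p-values measure the spread between these samples. By the dates in the titles, 20 libraries of days 2 to 7 fall into culture courses, runs whose dates follow the day numbers. The 3 libraries of each of days 3, 4, 5 and 6 come from the same 3 courses, so the steps between them are paired by date. The main fits did not use this pairing, and a block by culture course was an alternative. Levels are mean FPKM ± SD over libraries, and differences are on the log2(FPKM + 1) scale. Of 14595 genes tested, a gene was called at an adjusted p under 0.05 with a difference of at least 1 on that scale. For gene lists the adjusted p of camera is given with a preset correlation between genes, followed by the adjusted p with an estimated correlation, written as estimated adjusted p. Coordinates are those of mouse build mm9 as deposited.

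The first comparison asked what changed in the first 2 days, from stem cells in the medium 2i/LIF to epiblast-like cells. Effects of leaving that medium, on signalling targets among others, cannot be told apart from those of the change of cell state. Naive pluripotency genes fell together. Among them were Tfcp2l1, a transcription factor of the naive state (1.31 ± 0.236 against 148 ± 28.3 FPKM, log2 -6.00, SE 0.15, adjusted p = 1.32e-23), and Klf4, a reprogramming factor (1.18 ± 0.644 against 124 ± 18.8 FPKM, log2 -5.89, SE 0.23, adjusted p = 1.32e-19). Nanog fell too (19.7 ± 5.76 against 511 ± 36.5 FPKM, log2 -4.67, SE 0.27, adjusted p = 2.86e-15). Genes of the formative epiblast rose, such as Dnmt3b, a de novo DNA methyltransferase (546 ± 38.7 against 13.3 ± 2.74 FPKM, log2 5.27, SE 0.18, adjusted p = 7.45e-21). Fgf5, a growth factor of the epiblast, rose from near 0 (23 ± 4.94 against 0.202 ± 0.0512 FPKM, log2 4.30, SE 0.32, adjusted p = 7.37e-13). Pou5f1, which encodes the pluripotency factor Oct4, did not pass (1104 ± 31.6 against 1235 ± 62.5 FPKM, log2 -0.16, SE 0.27, adjusted p = 0.671). Sox2 fell (29.9 ± 6.83 against 229 ± 12.6 FPKM, log2 -2.92). In all, 1122 genes were higher and 1327 lower at day 2 (n = 5 against 3), 2449 of 14595. Of all genes tested, called or not, 8168 (56%) had no overlap between the libraries of the 2 groups, where chance gives 3.57% for 5 against 3.

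Among the largest rises were Pim2, a serine/threonine kinase (839 ± 53.9 against 11.5 ± 0.823 FPKM, log2 6.07; XLOC_023008, chromosome X, 7455432 to 7460558), and Car4, a carbonic anhydrase (67.8 ± 9.78 against 0.0454 ± 0.0786 FPKM, log2 6.03; XLOC_002992, chromosome 11, 84771256 to 84779556). Others were Tmem54 (log2 5.84), the epithelial splicing regulator Esrp1 (54.6 ± 4.62 against 0.136 ± 0.0537 FPKM, log2 5.61), Vrtn (log2 5.06) and Emb, also called embigin (181 against 4.51 FPKM). Xist, the RNA that coats the inactive X chromosome (XLOC_023854, chromosome X, 100655712 to 100678572), rose from 0.48 ± 0.216 to 48.5 ± 10.8 FPKM (log2 5.05, SE 1.05, adjusted p = 0.000149). The fit takes the spread of each gene from all groups, and the unlike MEF cultures widen that of Xist in every comparison. Among the largest falls were Aqp3, a water channel (0.368 ± 0.226 against 254 ± 84 FPKM, log2 -7.50; XLOC_014972, chromosome 4, 41039757 to 41045216), and the junction protein gene Jam2 (log2 -6.32). Others were Nr0b1 (2.35 ± 0.901 against 163 ± 25.4 FPKM, log2 -5.64) and Tdh, which encodes threonine dehydrogenase (8.48 against 431 FPKM, log2 -5.52).

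Of the 15 naive pluripotency genes tested, 14 fell and 0 rose (camera adjusted p = 2.84e-17, estimated adjusted p = 0.00727). Falls of the list included Prdm14 (log2 -5.43), Tbx3 (log2 -5.45), Tfcp2l1 (1.31 against 148 FPKM, log2 -6.00) and Klf4 (log2 -5.89). Of 14 formative and primed epiblast genes, 11 rose and 0 fell (camera adjusted p = 2.2e-09, estimated adjusted p = 0.011). They included Pou3f1 (72.8 against 1.89 FPKM, log2 4.67), Dnmt3a (100.3 against 3.17 FPKM, log2 4.60) and Otx2 (log2 3.84). Among 6 Wnt targets, 4 fell, Notum (log2 -5.31), Sp5 (log2 -4.56) and Axin2 (log2 -1.74) among them, and 0 rose (camera adjusted p = 0.0281, estimated adjusted p = 0.497). The other lists did not pass as sets. General pluripotency genes went both ways, 4 up, with Lin28a (218 against 8.49 FPKM, log2 4.56) and Utf1 (517 against 53.1 FPKM, log2 3.28), and 1 down (camera adjusted p = 0.127, estimated adjusted p = 0.959). FGF and ERK targets held 4 rises, with Dusp6 (log2 4.75) and Spry4 (log2 2.64), and 1 fall (camera adjusted p = 0.0615, estimated adjusted p = 0.584). Among germline genes Mael (log2 3.71) and Ddx4 (log2 2.53) rose and Dazl fell (log2 -3.49). The DNA replication list held 1 fall in 18 genes. Rif1, a regulator of replication timing, did not pass (61 ± 3.65 against 56.3 ± 6.77 FPKM, log2 0.12, SE 0.15, adjusted p = 0.551). Counts adjusted over the list alone equalled those over all genes in every list of this comparison. Within sequencing project A, which holds all day 0 libraries, 2477 genes were called (3 against 3). Project B holds no day 0 library.

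**Figure D1:**
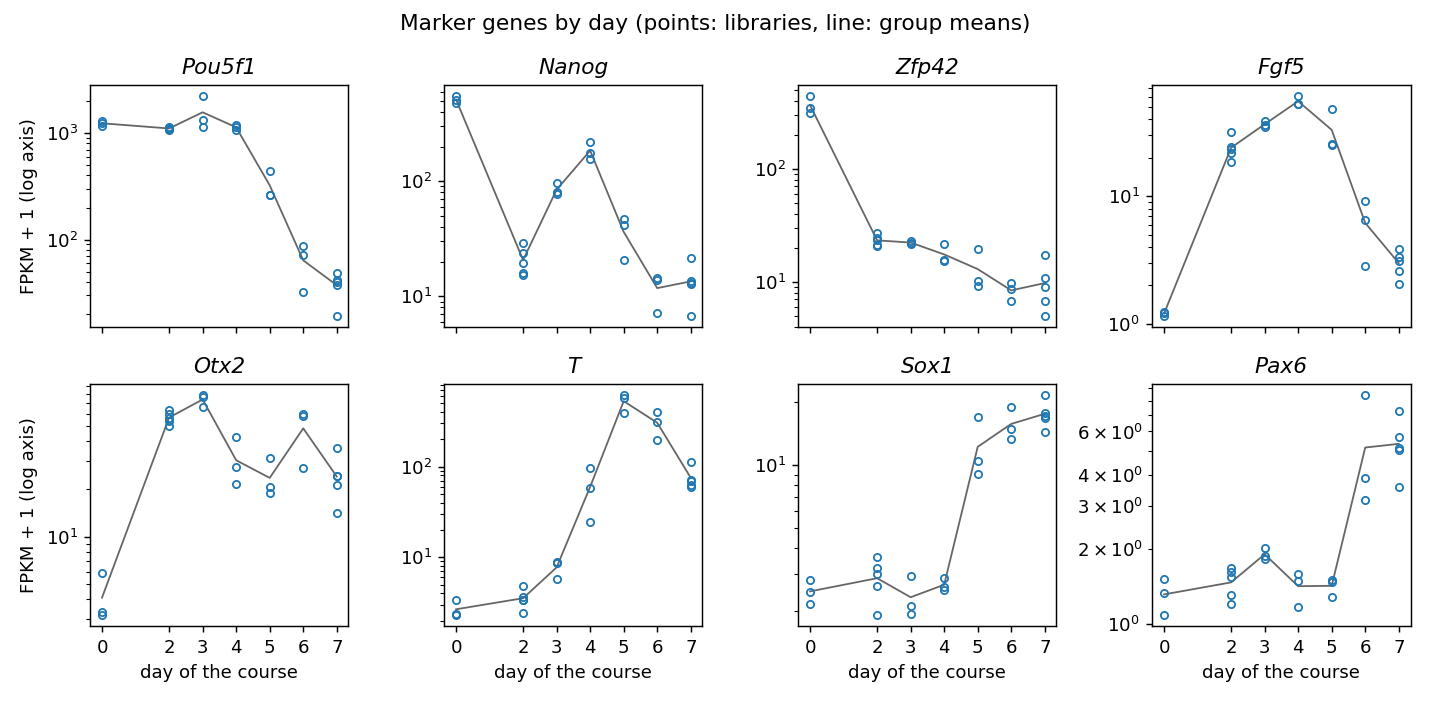
FPKM on a log scale, plotted as FPKM + 1, of 8 of the genes fixed in advance at days 0 to 7 of the course, with points for libraries and lines through the group means. Nanog fell from a mean of 511 to 19.7 FPKM by day 2. Pou5f1 stood at 1131 FPKM at day 4 and 36.3 at day 7. T was highest at day 5, at 528 FPKM.

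The second comparison asked what the 5 days of aggregate culture changed, from day 2 to day 7. Neural genes rose, among them Sox1, an early neural transcription factor (16.6 ± 2.64 against 1.87 ± 0.646 FPKM, log2 2.64, SE 0.21, adjusted p = 1.5e-12). Fabp7, a fatty acid binding protein of radial glia, rose further (64.8 ± 17.2 against 0.239 ± 0.232 FPKM, log2 5.70, SE 0.25, adjusted p = 1.2e-18), as did Cdh2, which encodes N-cadherin (53.5 ± 6.06 against 1.88 ± 0.236 FPKM, log2 4.24, SE 0.14, adjusted p = 1.39e-21). Most general pluripotency genes fell, among them Pou5f1 (36.3 ± 10.9 against 1104 ± 31.6 FPKM, log2 -4.96, SE 0.24, adjusted p = 1.07e-17) and Utf1 (9.87 ± 3.08 against 517 ± 31 FPKM, log2 -5.63, SE 0.20, adjusted p = 6.7e-21). Sox2 rose, and the list as a set lost its call with an estimated correlation. Rif1 fell as well (22.8 ± 1.04 against 61 ± 3.65 FPKM, log2 -1.38, SE 0.13, adjusted p = 7.53e-11). At day 7 2200 genes were higher and 1604 lower (n = 5 against 5), 3804 in all. Among all genes tested 9024 (61.8%) had no overlap between the libraries, where chance gives 0.794% for 5 against 5.

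Among the largest rises were the imprinted RNA gene H19, listed with Mir675 (1095 ± 351 against 9.2 ± 2.1 FPKM, log2 6.71; XLOC_020426, chromosome 7, 149761435 to 149764051), and Shh, the signal of the notochord and floor plate (81.3 ± 33.7 against 0.0134 ± 0.0300 FPKM, log2 6.26; XLOC_016398, chromosome 5, 28783380 to 28793641). Others were the imprinted gene Nnat (663 ± 84 against 8.21 ± 2.04 FPKM, log2 6.19) and Nkx6-1, a factor of the ventral neural tube (61.8 ± 16.9 against 0.0247 ± 0.0553 FPKM, log2 5.90). Arg1, an enzyme of the urea cycle, Vtn and Spink1 were listed at 0 in all 5 day 2 libraries and stood at 73.5, 58.4 and 53.7 FPKM at day 7. The deepest falls included Pim2 (log2 -6.20), L1td1, which encodes an RNA binding protein of pluripotent cells (log2 -5.68), and Dnmt3l (1.77 ± 0.753 against 141 ± 47.1 FPKM, log2 -5.66). They also included the Nodal coreceptor gene Tdgf1 (7.14 ± 3.07 against 283 ± 26.7 FPKM, log2 -5.21) and Lefty1, an inhibitor of Nodal (log2 -5.09).

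Of 13 neural progenitor genes 11 rose and 0 fell (camera adjusted p = 4.23e-07, estimated adjusted p = 0.00114), with Sox21 (21.7 against 0.608 FPKM, log2 3.83) and Zfp521 (8.03 against 0.218 FPKM, log2 2.90) among them. Sox2 rose from 29.9 to 89.3 FPKM. Of 13 neuron genes 12 rose and 0 fell, with Elavl4 (30.9 against 0.603 FPKM, log2 4.30) and Nhlh1 (16.9 against 0.032 FPKM, log2 4.09) among them. The call of this list was lost with an estimated correlation (camera adjusted p = 6.02e-07, estimated adjusted p = 0.0712). General pluripotency genes fell in 11 of 13 cases and rose in 1, which was Sox2 (camera adjusted p = 2.5e-07, estimated adjusted p = 0.0893). Formative genes fell in 11 and rose in 1 of 14 (camera adjusted p = 0.000218, estimated adjusted p = 0.103). Dnmt3b stood at 18.5 against 546 FPKM, and Fgf5 fell (log2 -3.01). All 6 Nodal and Activin targets tested fell (camera adjusted p = 0.000281, estimated adjusted p = 0.154), for example Nodal (3.04 against 60.6 FPKM, log2 -3.98) and Foxh1 (6.65 against 76.6 FPKM, log2 -3.39). BMP targets rose in 4 of 6, with Id1 (66.8 against 2.19 FPKM, log2 4.42) and Id3 (211 against 5.22 FPKM, log2 5.09) (camera adjusted p = 0.00388, estimated adjusted p = 0.159).

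Endoderm genes rose in 6 and fell in 1 of 10 (camera adjusted p = 0.00791, estimated adjusted p = 0.163), with Foxa2 (59.5 against 0.445 FPKM, log2 5.37) and Cxcr4 (31.9 against 0.864 FPKM, log2 4.14). Fibroblast and mesenchyme genes rose in 13 and fell in 1 of 16 (camera adjusted p = 2.58e-05, estimated adjusted p = 0.103), with Col3a1 (37.4 against 0.246 FPKM, log2 4.87) and Acta2 (45.4 against 0.354 FPKM, log2 5.01). Primitive streak and mesoderm genes went both ways without passing as a set, 3 up and 3 down of 11 (camera adjusted p = 0.869, estimated adjusted p = 0.948). T, the mesoderm and notochord factor Brachyury, rose (74.3 ± 21.4 against 2.53 ± 0.864 FPKM, log2 4.41), and Wnt3 (0.605 against 8.34 FPKM, log2 -2.54) and Eomes (log2 -1.39) fell. The keratin gene Krt8 of the surface ectoderm list rose (202 against 42.8 FPKM). The posterior neural and Hox list held 4 rises in 9 genes, Hoxb2 (59.5 against 0.202 FPKM, log2 5.64) and Hoxb1 (25.1 against 0.357 FPKM, log2 4.26) among them, without passing as a set (camera adjusted p = 0.0541, estimated adjusted p = 0.37). Cholesterol synthesis genes fell in 7 of 8, with Fdps (log2 -2.07) and Insig1 (log2 -1.99; camera adjusted p = 7.53e-05, estimated adjusted p = 0.127). p53 targets fell in 5 of 7, with Phlda3 (log2 -2.02) and Cdkn1a (log2 -1.91; camera adjusted p = 0.00138, estimated adjusted p = 0.103). Germline genes fell in 6 of 8, with Mael (0.261 against 15.6 FPKM, log2 -3.68) (camera adjusted p = 0.000363, estimated adjusted p = 0.0893). In the DNA replication list 3 of 18 genes fell, Rif1 among them (camera adjusted p = 0.00277, estimated adjusted p = 0.557). Ctcf, the insulator protein gene, did not pass (41.2 ± 0.708 against 54.8 ± 4.76 FPKM, log2 -0.40, SE 0.09, adjusted p = 0.000142). The counts adjusted over the list alone did not differ here from those over all genes. Project A gave 3804 called genes (3 against 3) and project B gave 3854 (2 against 2).

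Over the whole course, from day 0 to day 7, naive genes fell and genes of neural progenitors and neurons rose. The widest rises included H19 (1095 ± 351 against 0.741 ± 0.206 FPKM, log2 9.25, SE 0.32), Nnat (log2 8.23) and Igfbp5, a binding protein of insulin-like growth factors (275 ± 37.6 against 0.366 ± 0.123 FPKM, log2 7.65; XLOC_000854, chromosome 1, 72904639 to 72921439). Others were Crabp2, which binds retinoic acid (324 against 1.5 FPKM, log2 6.99), Igf2 (140 ± 40.9 against 0.93 ± 0.371 FPKM, log2 6.16) and the carbonic anhydrase gene Car14 (log2 6.08). The short RNA locus Mir3072 was listed at 0 in all 5 day 7 libraries against 224 FPKM. Aqp3 (log2 -6.60), Lefty2 (4.88 against 471 FPKM, log2 -6.38), Klf4 (log2 -6.11), Tdgf1 (log2 -6.10) and Tfcp2l1 (log2 -6.06) fell furthest among the other genes. Pou5f1 fell by day 7 (36.3 ± 10.9 against 1235 ± 62.5 FPKM, log2 -5.12, SE 0.27, adjusted p = 1.4e-16; XLOC_008827, chromosome 17, 35642977 to 35647722). So did Nanog (12.5 ± 5.24 against 511 ± 36.5 FPKM, log2 -5.34, SE 0.27, adjusted p = 4.3e-17) and Sox2 (log2 -1.35), which lost its call with quantile normalization. The day 7 libraries had 2362 genes higher and 1841 lower than day 0 (n = 5 against 3), 4203 in all. Libraries did not overlap in 68.4% of all genes tested, against 3.57% by chance.

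All 15 naive genes tested fell (camera adjusted p = 9.64e-13, estimated adjusted p = 0.0172), Zfp42 (8.71 against 364 FPKM, log2 -5.35) and Esrrb (5.52 against 315 FPKM, log2 -5.63) among them. Neural progenitor genes rose in 10 of 13 (camera adjusted p = 5.44e-05, estimated adjusted p = 0.0146), with Sox11 (57.9 against 2.82 FPKM, log2 3.94) and Fabp7 (log2 5.99). Neuron genes rose in 12 and fell in 1 of 13 (camera adjusted p = 9.38e-07, estimated adjusted p = 0.0479). The neuron gene Dcx was listed at 0 in the 3 day 0 libraries and stood at 6.68 FPKM at day 7. General pluripotency genes fell in 10 and rose in 1 of 13 (camera adjusted p = 5.44e-05, estimated adjusted p = 0.235). Fibroblast genes rose in 12 and fell in 1 of 16, with Col1a2 at 14.9 against 0.705 FPKM (camera adjusted p = 2.11e-05, estimated adjusted p = 0.16). Endoderm genes rose in 6 and fell in 1 of 10, with Foxa2 (log2 5.68; camera adjusted p = 0.0336, estimated adjusted p = 0.321). Nodal and Activin targets fell in 5 of 6 (camera adjusted p = 0.00342, estimated adjusted p = 0.321). Wnt targets fell in 4 and rose in 1 of 6 (camera adjusted p = 0.0497, estimated adjusted p = 0.376).

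Genes of metabolism and replication fell in part, in lists that lost their call with an estimated correlation. Glycolysis genes fell in 6 of 14, with Pfkp (6.91 against 120 FPKM, log2 -3.95) and Aldoa (546 against 1671 FPKM, log2 -1.64) (camera adjusted p = 0.0171, estimated adjusted p = 0.543). Cholesterol genes fell in 4 of 8 (camera adjusted p = 0.00199, estimated adjusted p = 0.321). Germline genes fell in 4 of 8, with Dazl (0.677 against 90.5 FPKM, log2 -5.75) (camera adjusted p = 0.0098, estimated adjusted p = 0.235), and p53 targets in 3 of 7 (camera adjusted p = 0.0364, estimated adjusted p = 0.321). The DNA replication list fell in 4 of 18 (camera adjusted p = 0.0221, estimated adjusted p = 0.671). Rif1 stood at 22.8 ± 1.04 against 56.3 ± 6.77 FPKM (XLOC_011327, chromosome 2, 51928357 to 51977901). In the chromatin list, which did not pass as a set, the Polycomb genes Suz12 (26.4 against 102 FPKM, log2 -1.91) and Eed (log2 -1.30) fell and the methyltransferase gene Suv39h1 rose (log2 2.54). Ctcf did not pass (41.2 ± 0.708 against 41.5 ± 2.23 FPKM, log2 -0.01, SE 0.10, adjusted p = 0.946). Xist rose (95.9 ± 22.9 against 0.48 ± 0.216 FPKM, log2 6.01, SE 1.05, adjusted p = 8.37e-06). Its antisense gene Tsix fell (0.721 against 5.62 FPKM, log2 -1.92), with an uncertain level since the 2 overlap. None of the 4 X escape genes passed. Adjusted over the list alone, counts were the same except for the replication-dependent histones, with 2 rises over all genes and 1 adjusted over the list alone. Project A gave 4199 called genes (3 against 3).

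Across days 0 to 7, 7963 of 14595 genes (54.6%) changed at some day by the moderated F test. Of these 2045 (25.7%) had their highest mean at day 0 and 2026 (25.4%) at day 7. Between these, 947 were highest at day 2, 997 at day 3, 272 at day 4, 893 at day 5 and 783 at day 6.

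**Figure D2:**
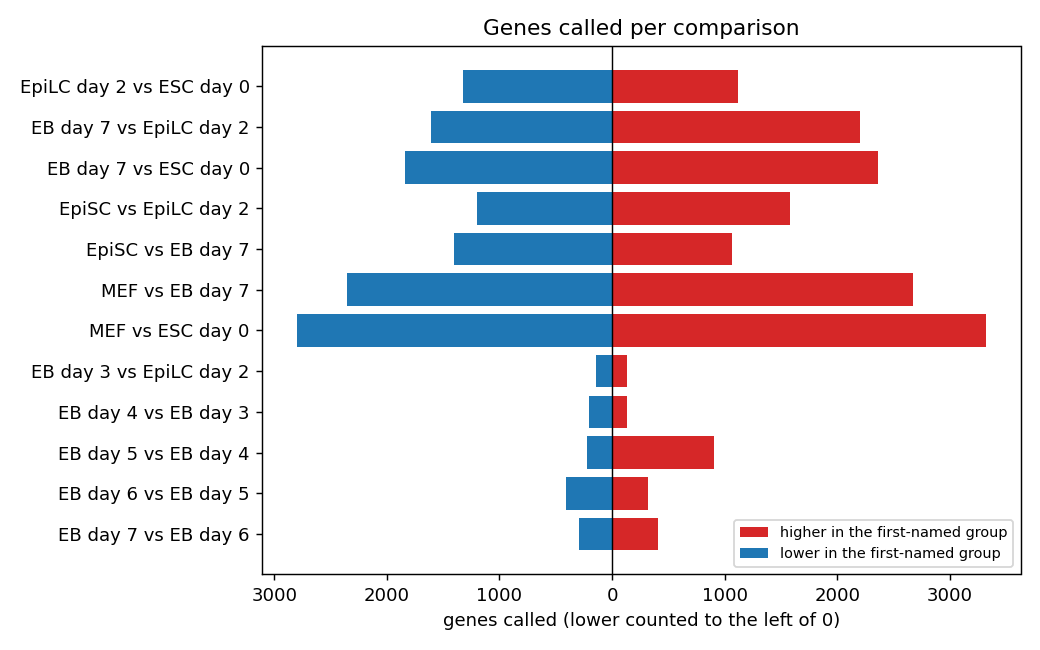
Number of genes called higher (bars to the right) and lower (bars to the left) in the first-named group of each of the 12 comparisons, of 14595 genes tested. The fewest, 273, were called between days 2 and 3 and the most, 6121, between MEF and day 0.

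The steps of 1 day asked when the changes fell. From day 2 to day 3, Trh, which encodes thyrotropin-releasing hormone, rose (1812 ± 869 against 27.3 ± 11.9 FPKM, log2 5.98, SE 0.35, adjusted p = 5.52e-13; XLOC_017999, chromosome 6, 92192055 to 92194644). So did the Wnt processing gene Porcn (log2 3.05). The short RNA locus Mir3072 stood at 208 ± 3.51 against 33.2 ± 74.3 FPKM (log2 6.23, SE 1.94, adjusted p = 0.0203). Its day 2 mean came from 1 library, replicate 5, at 166 FPKM, with 0 in the other 4, and without that library the difference was log2 7.71. Mir3072 lost its call without EB day 3 replicate 3 and with a block by culture course, and T lost its call without EB day 3 replicate 2 or 3. Ppp2r2c (log2 -1.88), Gpat2 (log2 -1.86) and Nupr1 (log2 -1.83) fell. Nanog rose again, from 19.7 to 83.5 FPKM (log2 2.07, adjusted p = 3.58e-06), and T from 2.53 to 6.73 FPKM. Cholesterol synthesis genes fell in 4 of 8 (camera adjusted p = 4.02e-10, estimated adjusted p = 0.0563). Germline genes fell in 3 and rose in 1 of 8 (camera adjusted p = 0.0243, estimated adjusted p = 0.515). In all 273 genes were called (n = 3 against 5), 133 higher and 140 lower, and 21.7% of all genes tested had no overlap (3.57% by chance). Leaving out EB day 3 replicate 1 gave 446, and project B gave 394 (2 against 2). EB day 3 replicate 3 stood apart, with more RNA of glycolysis genes and 34.2% of its FPKM in ribosomal protein genes, the highest of all 34 libraries, against 26.2% and 27% in the others of the day. Its FPKM sum was 990727, against 618889 and 667299 in the other 2 libraries of the day.

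From day 3 to day 4, Foxa2, a factor of endoderm, notochord and floor plate (41 ± 15.8 against 3.58 ± 0.992 FPKM, log2 3.15, SE 0.39, adjusted p = 1.64e-06; XLOC_012826, chromosome 2, 147868613 to 147872705), and T (59 ± 36 against 6.73 ± 1.78 FPKM, log2 2.77, SE 0.41, adjusted p = 1.79e-05) were among the largest rises, with the actin gene Acta1 (log2 2.42). Gadd45g (log2 -2.43), Fgf4 (10.1 against 45.3 FPKM) and Cox7b2 (log2 -2.08) were among the largest falls. Nanog rose further, to 183 FPKM (log2 1.12, adjusted p = 0.0141), and Otx2 fell (log2 -1.33). Germline genes fell in 7 of 8 (camera adjusted p = 1.4e-11, estimated adjusted p = 0.000774). General pluripotency genes fell in 5 of 13 (camera adjusted p = 3.33e-07, estimated adjusted p = 0.0891). Posterior neural and Hox genes rose in 6 of 9 (camera adjusted p = 2.69e-05, estimated adjusted p = 0.0891). Primitive streak and mesoderm genes rose in 4 of 11, 5 adjusted over the list alone (camera adjusted p = 5.1e-05, estimated adjusted p = 0.0891). Wnt targets rose in 2 of 6 (camera adjusted p = 0.00104, estimated adjusted p = 0.0891) and neural progenitor genes in 1 of 13 (camera adjusted p = 0.0259, estimated adjusted p = 0.0891). No p53 target passed although the set did (camera adjusted p = 0.00104, estimated adjusted p = 0.0891). Of the 335 genes called (n = 3 against 3), 133 were higher and 202 lower. Libraries did not overlap in 3855 (26.4%) of all genes tested, against 10% by chance. A fit of these 2 groups alone called 168, without Cox7b2, Otx2 and T, and Nanog lost its call without EB day 4 replicate 1. Project B alone gave 363 (2 against 2).

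From day 4 to day 5 the calls went mostly upwards, 908 higher and 226 lower (n = 3 against 3), 1134 in all, and 44% of all genes tested had no overlap (10% by chance). Spink1, a trypsin inhibitor (88.8 ± 16.2 against 0.238 ± 0.413 FPKM, log2 6.21, SE 0.24, adjusted p = 1.85e-18), Arg1 (log2 5.83) and Gal, which encodes the neuropeptide galanin (185 against 2.91 FPKM), rose most. Tmem54 (log2 -2.62), Utf1 (24.5 against 142 FPKM) and Foxi3 (log2 -2.45) were among the largest falls. T reached its highest mean, 528 ± 124 FPKM (XLOC_008518, chromosome 17, 8627288 to 8635361). The endoderm factor gene Sox17 rose from 0.0464 to 12.2 FPKM and Sox1 from 1.67 to 11.2. Pou5f1 fell from 1131 to 322 and Nanog from 183 to 35.2 FPKM. Rif1 had a difference under the minimum (31.6 ± 4.15 against 54.2 ± 5.53 FPKM, log2 -0.76, SE 0.17, adjusted p = 0.000773). Of 14 lists that passed, 2 of them with an estimated correlation, neural progenitor genes rose in 6 of 13 (camera adjusted p = 2.38e-05, estimated adjusted p = 0.00913) and endoderm genes in 5 of 10 (camera adjusted p = 1.75e-05, estimated adjusted p = 0.0496). General pluripotency genes fell in 7 of 13 (camera adjusted p = 3.31e-07, estimated adjusted p = 0.0626). Of called genes 80.1% were higher, against 65.3% after quantile normalization. Project B alone gave 1095 called genes (2 against 2).

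From day 5 to day 6 primitive streak and mesoderm genes fell in 8 of 11 and rose in 0 (camera adjusted p = 7.35e-10, estimated adjusted p = 0.0106). Pou5f1 fell to 62.8 FPKM (log2 -2.42). Among the largest falls were Msgn1, a factor of presomitic mesoderm (0.408 ± 0.416 against 23.1 ± 9.06 FPKM, log2 -4.08, SE 0.17, adjusted p = 2.97e-17), and Mixl1, a factor of the primitive streak (log2 -3.70). Foxj1, a factor of motile cilia, also fell (5.78 against 82.9 FPKM). Among the largest rises were Capn6 (log2 3.90) and H19 (776 against 57.8 FPKM). Pax6, an eye and neural tube factor, rose from 0.424 to 4.17 FPKM. Among 13 lists that passed, 1 of them with an estimated correlation, was general pluripotency, with 7 falls in 13 (camera adjusted p = 9.28e-08, estimated adjusted p = 0.112). Nodal and Activin targets held 5 falls in 6 (camera adjusted p = 9.3e-05, estimated adjusted p = 0.152), and fibroblast genes 4 rises in 16 (camera adjusted p = 1.73e-05, estimated adjusted p = 0.122). Formative genes fell in 5, 6 adjusted over the list alone. In all 319 genes were higher and 405 lower, 724 in total (n = 3 against 3), and 26.2% of all genes tested had no overlap (10% by chance). Project B alone gave 771 (2 against 2).

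From day 6 to day 7 neuron genes rose in 11 of 13 (camera adjusted p = 4.91e-23, estimated adjusted p = 0.000125). Nefm, a neurofilament gene, rose most (72.6 ± 8.14 against 1.77 ± 0.134 FPKM, log2 4.73, SE 0.24, adjusted p = 6.23e-16; XLOC_006744, chromosome 14, 68737602 to 68743061), with Rgs4 (log2 4.37) and Ppp1r17 (log2 4.12). The Nodal coreceptor gene Cfc1 (1.61 against 43 FPKM), the notochord factor gene Noto (0.675 against 25.7 FPKM) and the RNA gene Hoxaas3 (log2 -3.39) were among the largest falls. T fell from 304 to 74.3 FPKM. Fibroblast genes rose in 5 of 16 (camera adjusted p = 0.00207, estimated adjusted p = 0.376) and neural progenitor genes in 3 of 13 (camera adjusted p = 0.0106, estimated adjusted p = 0.104). Primitive streak genes fell in 5 of 11 (camera adjusted p = 0.0108, estimated adjusted p = 0.376) and formative genes in 4 of 14 (camera adjusted p = 0.0129, estimated adjusted p = 0.387). Endoderm genes fell in 3 of 10 (camera adjusted p = 0.0387, estimated adjusted p = 0.409), surface ectoderm genes in 2 of 7 (camera adjusted p = 0.0387, estimated adjusted p = 0.376). Blood and endothelium genes rose in 3 of 8, 4 adjusted over the list alone (camera adjusted p = 0.0387, estimated adjusted p = 0.498). Of the 700 genes called (n = 5 against 3), 408 were higher and 292 lower, and 29.4% of all genes tested had no overlap (3.57% by chance). T lost its call with project B alone, which gave 623 (2 against 2).

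EpiSC, by the titles another line than CBMS1, were compared with day 2 cells. In every comparison of EpiSC, line, medium and feeders cannot be told apart from cell state. EpiSC had less of the pluripotency-associated genes Dppa5a (0.597 ± 0.45 against 758 ± 121 FPKM, log2 -8.91, SE 0.32, adjusted p = 2.62e-20; XLOC_022733, chromosome 9, 78214861 to 78216006) and Dppa4 (0.231 ± 0.185 against 121 ± 8.19 FPKM, log2 -6.64, SE 0.17, adjusted p = 6.95e-24). They had more of Slc39a8, a metal ion transporter (169.8 ± 104 against 0.727 ± 0.14 FPKM, log2 6.43, SE 0.25, adjusted p = 1.9e-19; XLOC_013557, chromosome 3, 135488243 to 135551536), and of the collagen genes Col3a1 (89.4 ± 25.6 against 0.246 ± 0.149 FPKM, log2 6.15, SE 0.24, adjusted p = 1.57e-19) and Col1a1 (log2 5.86). The glycoprotein gene Cd59a (113 ± 26.6 against 0.517 ± 0.136 FPKM, log2 6.22), the matrix gene Bgn (log2 5.95), S100a4 (log2 5.79) and Cer1, a secreted inhibitor of Nodal and BMP (44.1 ± 20.3 against 0.178 ± 0.0844 FPKM, log2 5.14), were among the largest rises. The ribosomal protein gene Rps4l was among the largest falls (2.02 against 681 FPKM). Another, Rpl10l, was listed at 0 in the 3 EpiSC libraries against 111 FPKM. Both resemble other ribosomal protein genes, so their values are uncertain. Nanog (122 ± 32.7 against 19.7 ± 5.76 FPKM, log2 2.58), Sox2 (log2 1.42) and the nuclear receptor gene Nr5a2 (27.2 against 0.386 FPKM) were higher in EpiSC, and Zfp42 was lower (log2 -3.99). Pou5f1 (721 ± 245 against 1104 ± 31.6 FPKM, log2 -0.68, SE 0.27, adjusted p = 0.0349) and Fgf5 (31.5 ± 24.4 against 23 ± 4.94 FPKM, log2 0.21, SE 0.32, adjusted p = 0.594) did not pass. In EpiSC 1583 genes were higher and 1199 lower (n = 3 against 5), 2782 in all. Of all genes tested 7906 (54.2%) had no overlap, against 3.57% by chance.

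Fibroblast and mesenchyme genes were higher in 15 of 16 (camera adjusted p = 5.23e-11, estimated adjusted p = 0.018), with Postn (32.2 against 0.172 FPKM, log2 4.80) and Col1a2 (83.4 against 0.934 FPKM, log2 5.42). Those higher stood at a median of 4.37% of their MEF level. The 4 Y genes, none of which passed, stood at 3.26% to 4.87% of their level in the male MEF culture although the EpiSC are labelled female. Eif2s3y, for example, stood at 1.12 ± 0.0791 FPKM in EpiSC. The fit takes the spread of each gene from all groups, and Eif2s3y had a mean of 0 FPKM in MEF culture 1 and 30.4 in culture 2. That the Y genes did not pass therefore says little. A share of the MEF level was then taken away from each library, 3.37% to 5.54%, the median over 15 fibroblast genes, which left 1286 genes higher and 2667 called. Genes below that share go to 0 by construction, as did Postn (log2 -0.22), Col1a2 (log2 -0.95), Col1a1 (log2 -0.74) and Bgn (log2 -0.77) in all 3 libraries, which turned their direction. Germline genes were lower in 7 of 8 (camera adjusted p = 1.09e-07, estimated adjusted p = 0.0112), with Tex19.1 (2.64 against 84.7 FPKM, log2 -4.47) and Ddx4 (0.285 against 9.22 FPKM, log2 -2.99). Mael was listed at 0 in the 3 EpiSC libraries against 15.6 FPKM. General pluripotency genes were lower in 7 and higher in 1 of 13 (camera adjusted p = 0.000198, estimated adjusted p = 0.333), with Dppa2 (log2 -5.23). Formative genes were lower in 8 and higher in 1 of 14 (camera adjusted p = 0.00918, estimated adjusted p = 0.344), with Dnmt3b (log2 -2.45) and Pou3f1 (log2 -3.52). Cholesterol genes were lower in 5 of 8, with Fdps (log2 -1.65) and Lss (log2 -1.61; camera adjusted p = 0.000298, estimated adjusted p = 0.333).

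Neural progenitor genes were higher in 6 of 13, with Zfp521 (9.39 against 0.218 FPKM, log2 3.06) (camera adjusted p = 0.036, estimated adjusted p = 0.259). Endoderm genes were higher in 4 and lower in 1 of 10 (camera adjusted p = 0.036, estimated adjusted p = 0.365). Lists that did not pass as sets still held calls. Naive genes were higher in 3 and lower in 7 of 15, with Dppa3 (log2 -4.96). The immediate early genes Fos (63.3 ± 61 against 2.98 ± 4.1 FPKM, log2 3.74, SE 0.63), Jun (log2 2.42) and Junb (log2 1.82) were higher. In glycolysis, Slc2a3 (330.4 against 22 FPKM, log2 3.77), Slc2a1 (505 against 73.2 FPKM, log2 2.64) and Pgk1 (1239 against 421 FPKM, log2 1.54) were higher. Xist did not pass (60.4 ± 14.1 against 48.5 ± 10.8 FPKM, log2 0.31, SE 1.05, adjusted p = 0.822), nor did Rif1 (55.3 ± 7.97 against 61 ± 3.65 FPKM, log2 -0.15, SE 0.15, adjusted p = 0.423). The SE of Xist was widened by the MEF libraries in the fit, with 0 FPKM in replicate 2 and 93.1 in replicate 5. It does not measure the spread of EpiSC and day 2 libraries alone. Counts adjusted over the list alone were equal to those over all genes. Within project B, which holds all EpiSC libraries, 2860 genes were called (3 against 2).

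By 1 minus Pearson r across genes, the mean of day 4 was nearest to EpiSC (0.0756 ± 0.0148, mean ± SD over 3 libraries). Day 5 (0.0857 ± 0.015), day 6 (0.0913 ± 0.00856) and day 3 (0.0954 ± 0.0136) followed. Farther off were day 2 (0.104 ± 0.0132), day 7 (0.105 ± 0.00627) and day 0 (0.152 ± 0.00802). In each library day 4 was the nearest.

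**Figure D3:**
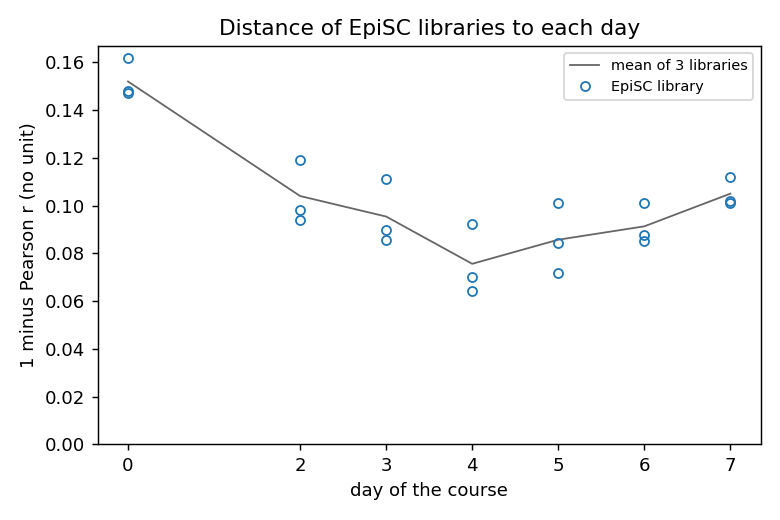
Distance, as 1 minus Pearson r across 14595 genes, of each of the 3 EpiSC libraries (points) to the mean of each day of the course, with a line through the means. The mean was lowest at day 4, 0.0756, and highest at day 0, 0.152.

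EpiSC were compared with day 7 cells, the neurectoderm end point. EpiSC had more of the Nodal pathway genes Tdgf1 (525 ± 138 against 7.14 ± 3.07 FPKM, log2 6.07, SE 0.25, adjusted p = 5.43e-19; XLOC_022890, chromosome 9, 110842112 to 110848662) and Lefty1 (421 ± 322 against 7.32 ± 1.48 FPKM, log2 5.04, SE 0.43, adjusted p = 2.9e-11) and of Pou5f1 (721 ± 245 against 36.3 ± 10.9 FPKM, log2 4.28, SE 0.27, adjusted p = 3.49e-14). They had less of Nkx2-9, a factor of the ventral neural tube (0.0576 ± 0.0998 against 78.5 ± 13.9 FPKM, log2 -6.22, SE 0.24, adjusted p = 1.4e-19; XLOC_004818, chromosome 12, 57712384 to 57714271), and Hoxb2, a hindbrain patterning gene (0.0414 ± 0.0717 against 59.5 ± 8.92 FPKM, log2 -5.85, SE 0.24, adjusted p = 1.06e-18). Cd59a (log2 5.43), S100a4 (log2 5.99), Ly6a (log2 4.61) and Bgn (log2 4.59) were also higher. With the fibroblast share taken away Bgn, which lay below that share and so went to 0, turned to log2 -2.13. Mmp3, a matrix protease, was listed at 0 in all 5 day 7 libraries against 35.9 FPKM in EpiSC. Nkx6-2 and the RNA gene Hotairm1 were listed at 0 in the 3 EpiSC libraries against 61.1 and 59.4 FPKM at day 7. Arg1 was lower (log2 -6.01). Rif1 was higher in EpiSC (55.3 ± 7.97 against 22.8 ± 1.04 FPKM, log2 1.23, SE 0.15, adjusted p = 3.45e-08). Sox2 did not pass (80 ± 5.17 against 89.3 ± 6.91 FPKM, log2 -0.15, SE 0.18, adjusted p = 0.503). In all 1066 genes were higher and 1399 lower (n = 3 against 5), 2465 together, and 48% of all genes tested had no overlap (3.57% by chance). Project B alone gave 2463 (3 against 2).

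Neuron genes were lower in 12 and higher in 1 of 13 (camera adjusted p = 5.9e-11, estimated adjusted p = 0.00693). Nhlh1 was listed at 0 in the 3 EpiSC libraries against 16.9 FPKM. Neural progenitor genes were lower in 9 of 13 (camera adjusted p = 1.82e-06, estimated adjusted p = 0.0021), with Fabp7 (1.75 against 64.8 FPKM, log2 -4.75) and Sox1 (2.15 against 16.6 FPKM, log2 -2.63). Posterior neural and Hox genes were lower in 5 and higher in 1 of 9 (camera adjusted p = 0.00235, estimated adjusted p = 0.236). All 6 Nodal and Activin targets tested were higher (camera adjusted p = 1.53e-05, estimated adjusted p = 0.182), with Foxh1 (57.6 against 6.65 FPKM, log2 2.99) and Nodal (36.6 ± 23.2 against 3.04 ± 1.09 FPKM). BMP targets were lower in 4 and higher in 1 of 6 (camera adjusted p = 0.0108, estimated adjusted p = 0.274), with Id2 (2.85 against 79.9 FPKM, log2 -4.52). Glycolysis genes were higher in 8 of 14, with Aldoa (1509 against 546 FPKM, log2 1.47) (camera adjusted p = 0.000142, estimated adjusted p = 0.396). Mitosis genes were higher in 4 of 12, with Ccnb2 (log2 1.38) and Cdk1 (log2 1.07, not called without EpiSC replicate 2; camera adjusted p = 0.00521, estimated adjusted p = 0.493), and p53 targets in 4 of 7, with Cdkn1a (log2 1.65; camera adjusted p = 0.0185, estimated adjusted p = 0.274). General pluripotency genes were higher in 5 and lower in 2 of 13 (camera adjusted p = 0.0329, estimated adjusted p = 0.493). Fibroblast genes were higher in 8 and lower in 2 of 16 (camera adjusted p = 0.0191, estimated adjusted p = 0.493), with Thy1 (log2 4.42) up and Twist1 (2.11 against 21.7 FPKM, log2 -2.78) down. T (2.87 against 74.3 FPKM), Cxcr4 (log2 -3.44) and Krt8 (log2 -2.44) were lower and Cer1 (log2 3.80) and Otx2 (log2 2.09) higher. Adjusted over the list alone, the counts of these lists were unchanged.

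MEF were compared with day 7 cells, to set the neurectoderm end point against a mesenchymal cell type. S100a4 and genes of the matrix were higher in MEF by the widest margins, with S100a4 first (1340 ± 764 against 0.0851 ± 0.19 FPKM, log2 10.12, SE 0.27, adjusted p = 1.34e-24; XLOC_013320, chromosome 3, 90407692 to 90409967). Lox, which crosslinks collagen (980.5 ± 119 against 0.354 ± 0.214 FPKM, log2 9.51, SE 0.12, adjusted p = 2.32e-32; XLOC_010113, chromosome 18, 52675714 to 52689521), and Col1a1 (4175 ± 506 against 6.44 ± 2.3 FPKM, log2 9.18, SE 0.19, adjusted p = 3.24e-27; XLOC_003043, chromosome 11, 94797584 to 94813170) were among the next. Others were Mgp (log2 9.67), Bgn (log2 9.33), Eln (log2 8.37), Postn (log2 8.05) and Col6a3 (log2 7.70). Krt8 (1.02 ± 0.552 against 202 ± 37.8 FPKM, log2 -6.68, SE 0.22, adjusted p = 1.72e-22; XLOC_007712, chromosome 15, 101827142 to 101834773), the RNA binding protein gene Lin28a (0.0254 against 103 FPKM, log2 -6.65), Cldn6 (log2 -6.54), Nnat (log2 -6.45), Bex1 (log2 -6.42) and Nkx2-9 (log2 -6.25) were among those lowest relative to day 7. Shh was listed at 0 in all 6 MEF libraries against 81.3 FPKM. Rif1 was lower in MEF (4.66 ± 1.09 against 22.8 ± 1.04 FPKM, log2 -2.09, SE 0.12, adjusted p = 7.89e-16). The nuclear lamina gene Lmna was higher (352 ± 47.6 against 5.56 ± 1.21 FPKM, log2 5.76, SE 0.16, adjusted p = 1.7e-24). In MEF 2670 genes were higher and 2355 lower (n = 6 against 5), 5025 in all. The 6 libraries are passages of 2 cultures. With the mean per culture 5010 genes were called, and 11562 of all genes tested (79.2%) had no overlap, where chance gives 9.52% for 2 against 5.

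All 16 fibroblast and mesenchyme genes were higher (camera adjusted p = 2.53e-10, estimated adjusted p = 0.0426). All 13 neuron genes were lower, with Elavl4 (0.129 against 30.9 FPKM, log2 -4.80) (camera adjusted p = 1.09e-07, estimated adjusted p = 0.0426). General pluripotency genes were lower in all 13 (camera adjusted p = 4.65e-07, estimated adjusted p = 0.164), Sox2 (0.699 against 89.3 FPKM, log2 -5.79) and Pou5f1 (0.306 against 36.3 FPKM, log2 -4.79) among them. Formative genes were lower in 9 and higher in 1 of 14 (camera adjusted p = 0.00161, estimated adjusted p = 0.205). Neural progenitor genes were lower in 8 and higher in 3 of 13, with Msi1 (log2 -4.61; camera adjusted p = 0.0399, estimated adjusted p = 0.205). DNA replication genes were lower in 17 of 18, with Mcm2 (23.6 against 91.9 FPKM, log2 -1.97), Mcm7 (log2 -2.36) and Mcm10 (log2 -2.36; camera adjusted p = 2.29e-06, estimated adjusted p = 0.378). Mitosis genes were lower in 11 of 12, with Bub1 (log2 -2.17; camera adjusted p = 0.00161, estimated adjusted p = 0.49). Chromosome architecture and heterochromatin genes were lower in 8 and higher in 1 of 23, with Ezh2 (log2 -2.50) and Suv39h2 (log2 -2.42; camera adjusted p = 5.34e-05, estimated adjusted p = 0.205). Cholesterol genes were higher in 7 of 8, with Insig1 (213 against 31.1 FPKM, log2 2.76) (camera adjusted p = 0.000435, estimated adjusted p = 0.205).

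Outside these sets, the naive factor gene Klf4 (55.6 against 0.806 FPKM), the neural crest genes Snai2 (log2 4.47) and Msx1 (log2 4.30) and the p53 target gene Phlda3 (log2 2.87) were higher. The glucose transporter gene Slc2a3 was lower (log2 -4.90). Immediate early genes were higher in 3, and in 2 adjusted over the list alone; the other lists kept their counts. Xist was lower (40.8 ± 45.2 against 95.9 ± 22.9 FPKM, log2 -3.37). That mean was of an uneven group, with 72.2 to 93.1 FPKM in the 3 libraries of MEF culture 1 and 0 to 0.0393 in those of culture 2. The 4 Y genes were higher over the group, which was uneven here too, with Ddx3y (14.7 ± 16.1 FPKM) at 0 to 0.0347 FPKM in culture 1 and 27.5 to 31.5 in culture 2. Its call was lost in the fit of 2 groups alone. Quantile normalization moved the median difference of all genes from -0.084 to -0.109. Project A alone gave 5016 called genes (6 against 3).

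MEF against day 0 cells gave the most calls, 3322 higher and 2799 lower (n = 6 against 3), 6121 in all. With the mean per MEF culture 6110 were called, and 12496 of all genes tested (85.6%) had no overlap, where chance gives 20% for 2 against 3. Bgn (2830 ± 361 against 0.488 ± 0.00607 FPKM, log2 10.88, SE 0.22, adjusted p = 1.8e-27), Col1a2 (3206 ± 604 against 0.705 ± 0.255 FPKM, log2 10.87, SE 0.20, adjusted p = 1.24e-28; XLOC_017001, chromosome 6, 4455697 to 4491543) and H19 (log2 10.67) were highest relative to day 0. Col3a1 (log2 10.20), Postn (log2 9.71) and Mgp (log2 9.69) were also higher. Dppa5a (0.0591 ± 0.145 against 3725 ± 431 FPKM, log2 -11.78, SE 0.31, adjusted p = 5.62e-25), Pou5f1 (0.306 ± 0.247 against 1235 ± 62.5 FPKM, log2 -9.91, SE 0.27, adjusted p = 1.11e-24), Tdgf1 (log2 -8.93), Tdh (log2 -8.71) and Nanog (log2 -8.69) were among the lowest. The epithelial cadherin gene Cdh1 was lower (log2 -7.26). Rif1 was lower (4.66 ± 1.09 against 56.3 ± 6.77 FPKM, log2 -3.35, SE 0.15, adjusted p = 2.09e-19), and Lmna was higher (352 against 9.49 FPKM).

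All 16 fibroblast genes were higher (camera adjusted p = 2.89e-11, estimated adjusted p = 0.0323). All 15 naive genes (camera adjusted p = 1.3e-09, estimated adjusted p = 0.0564) and all 13 general pluripotency genes (camera adjusted p = 1.3e-09, estimated adjusted p = 0.0564) were lower. DNA replication genes were lower in all 18, with Orc1 (log2 -2.98) and Mcm10 (log2 -3.13; camera adjusted p = 2.32e-07, estimated adjusted p = 0.29). So were mitosis genes in 11 of 12, with Ccnb1 (log2 -2.78; camera adjusted p = 0.00205, estimated adjusted p = 0.521), and glycolysis genes in 10 of 14, with Hk2 (log2 -2.60; camera adjusted p = 0.00198, estimated adjusted p = 0.432). Nodal and Activin targets were lower in 5 of 6 (camera adjusted p = 0.00335, estimated adjusted p = 0.29) and germline genes in 5 of 8, with Dazl (log2 -6.44; camera adjusted p = 0.00593, estimated adjusted p = 0.225). Chromosome architecture genes were lower in 10 and higher in 2 of 23, with Eed (log2 -2.12) and Lbr (log2 -2.11; camera adjusted p = 0.00335, estimated adjusted p = 0.332). Neural crest genes were higher in 6 of 8, with Snai2 (log2 4.40; camera adjusted p = 0.00589, estimated adjusted p = 0.0564), and BMP targets in 4 of 6, with Id1 (log2 4.59; camera adjusted p = 0.0231, estimated adjusted p = 0.29). Wnt targets were lower in 5 and higher in 1 of 6, with Tcf7 (log2 -4.06; camera adjusted p = 0.03, estimated adjusted p = 0.29). The X escape genes Eif2s3x (log2 -1.70) and Kdm6a (log2 -1.50) were lower. Counts adjusted over the list alone did not differ. Quantile normalization moved the median of all genes from -0.009 to -0.104. Project A, which holds all of these libraries, gave 6116 called genes when fitted alone.

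The stem cells and the EpiSC are female, so X-linked expression was compared with that of autosomes as the ratio of median FPKM. The ratio was taken over 466 X-linked and 12337 autosomal genes with a mean of at least 1 FPKM. The ratio was 1.22 ± 0.0643 at day 0 (n = 3), 0.965 ± 0.0773 at day 2, 0.954 ± 0.107 at day 3 and 0.979 ± 0.0539 at day 4. It then fell to 0.88 ± 0.069 at day 5, 0.835 ± 0.0343 at day 6 and 0.762 ± 0.0204 at day 7 (n = 5). Day 7 was lower than day 0 in all 5 libraries, with a difference of -0.462 and an exact two-sided permutation p of 0.0357, the smallest this design allows. Within project A the difference was -0.456, with an exact p of 0.1, again the smallest possible. EpiSC stood at 0.821 ± 0.0517 (difference from day 0 of -0.403, exact two-sided p = 0.1, the smallest possible for 3 against 3). EpiSC and day 0 were sequenced in different projects. At days 2 to 7, which hold both, the mean of project B less that of project A lay between -0.0913 and 0.0557. MEF stood at 0.738 ± 0.049 (difference -0.486, exact two-sided p = 0.0238, the smallest possible). The 6 MEF libraries are passages of 2 cultures, 1 of them male, and with the mean per culture the exact p was 0.2, the smallest possible for 2 against 3. Xist lay between 0.239 and 0.658 FPKM in the day 0 libraries and between 71.3 and 133 FPKM at day 7. The median X-linked gene fell by 0.26 on the log2 scale from day 0 to day 2 and by 0.58 to day 7. The medians of the 19 autosomes at day 7 lay between -0.09 and 0.19.

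**Figure D4:**
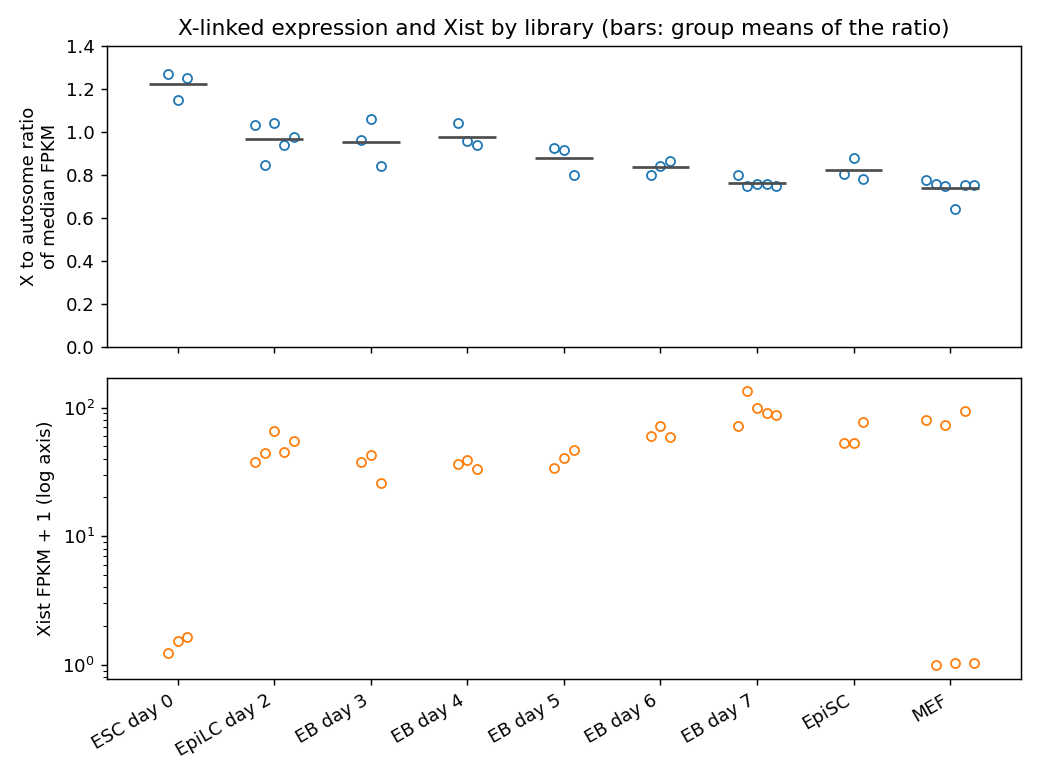
Ratio of median FPKM of 466 X-linked to 12337 autosomal genes (upper panel) and Xist FPKM, plotted as FPKM + 1 on a log axis (lower panel), in each of the 34 libraries, with bars at the group means of the ratio. The 3 day 0 libraries lay between 1.15 and 1.27, above all other libraries, and the 5 day 7 libraries between 0.749 and 0.798.

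Across comparisons, the calls of lists by camera that held with an estimated correlation were naive pluripotency and formative genes from day 0 to day 2 and neural progenitor genes from day 2 to day 7. From day 0 to day 7 naive, neural progenitor and neuron genes held, and in EpiSC against day 2 fibroblast and germline genes. Neuron and neural progenitor genes in EpiSC against day 7, fibroblast and neuron genes in MEF against day 7 and fibroblast genes in MEF against day 0 held too. Of the steps, germline genes at day 4, endoderm and neural progenitor genes at day 5, primitive streak genes at day 6 and neuron genes at day 7 held, and no list did at day 3.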

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

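The tests of the fibroblast genes in EpiSC, of the X to autosome ratio, of EB day 3 replicate 3 and of the splits by MEF culture were written only after the results were seen, while those of the splits of libraries were written before.

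Fibroblast genes were higher in EpiSC than at day 2, 15 of them at a median of 4.37% (2.14% to 12.7%) of their MEF level, and the 4 Y genes stood at a median of 3.96% (3.26% to 4.87%) of their level in the male MEF culture. A difference between sequencing projects was argued against, because the median of the list differed by -0.07 between projects at days 2 to 7 and by 3.41 between EpiSC and day 2. RNA of fibroblast feeder cells could put every fibroblast gene at about the Y share, and of 14 other genes with at least 100 FPKM in MEF and under 1 FPKM at each day, 9 (64.3%) lay within 3 times that share. The Y gene RNA would come from male cells, feeders or others, if the EpiSC are female as labelled. How much fibroblast RNA came from feeders and how much from the EpiSC themselves cannot be told apart, because no library of the feeder cells alone was in the set. Eln (0.301%), Ogn (0.218%), Nov (0.426%), Fbln5 (1%) and Lrrc17 (1.16%) lay below that range. They do not speak for expression by the EpiSC, which would add to the share. Whether feeder RNA gave most genes called higher in EpiSC cannot be told. With the share taken away 18.8% fewer genes were called higher, a net count. The share is a median, so genes above it, such as Tagln (12.7% of MEF), keep a rest that may be feeder RNA.

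The X to autosome ratio fell from day 0 to day 7, while Xist rose. A change of a few X-linked genes was argued against, because 68% of X-linked genes (317 of 466) were lower at day 7, against 39% to 54.8% of the genes of each autosome. Loss of an X chromosome in all cells was argued against by the lowest Xist level of the day 7 libraries, 71.3 FPKM. Silencing of 1 X chromosome would leave escape genes less changed, but the 4 listed ones had a median difference of -0.67, against -0.58 for all X-linked genes, a median above that of 41.2% of 10000 random sets. This lay within the spread of the random sets, so the test decides nothing. Silencing cannot be told apart from another wide fall because 4 genes are few and reads were not assigned to the 2 copies. The ratio of 0.762 at day 7 stood beside 0.717 in the male MEF culture and 0.76 in the other, but these are another cell type.

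EB day 3 replicate 3 stood apart from the other libraries of its day, and its 13 glycolysis genes with a known length lay at a median deviation of 0.92, with Pgk1 at 1325 against 321 and 345 FPKM and the genes Tpi1 and Bnip3, chosen after their values were seen, at 711 against 170 and 184 and at 50 against 10.8 and 12.1 FPKM. A trend with transcript length was present (Spearman rho of -0.53, against -0.32 to 0.35 in 12 libraries of other days), and whether it is the whole cause cannot be told apart, because the SD of 0.46 after its removal lay above those libraries (0.4 at most) but below EpiSC replicates 1 and 3 (0.48 and 0.47). For the glycolysis genes it was argued against, since with the trend removed their median was 0.99, above that of 100% of random lists matched on level and length. The labels give no treatment of that culture, so no biological explanation was tested.

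In every comparison only 1 split, the real one, reached the number of calls. This argues against chance where the splits are many enough and the libraries are separate samples. Between days 2 and 0 the real split called 2449 genes and the highest other 1077, between days 7 and 2 3804 and 1704, and between days 7 and 0 4203 and 2135. For EpiSC the counts were 2782 and 1119 against day 2 and 2465 and 999 against day 7. For the steps they were 273 and 74 from day 2 to day 3, 700 and 220 from day 6 to day 7, and for any change over the days 7963 and 4839. The MEF libraries are passages of 2 cultures, so their splits (5025 and 4036 against day 7, 6121 and 2775 against day 0) decide nothing. With the mean per culture, the real split against day 7, alone of 21, called 5010 genes and the highest other 7. That is the smallest share that 21 splits allow, from 2 cultures and a test written after the results were seen. Chance is therefore not excluded. Against day 0 (6110 and 3895) the 10 splits are too few for a share under 0.05. So are the 10 of each step to day 4 (335 and 1), day 5 (1134 and 1) and day 6 (724 and 107). Several of the highest other splits called many genes.

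Of 214 groups of 5 or 6 values tested by Dixon's ratio of gap to range, 16 (7.48%) held a library apart, where chance alone gives about 1 in 20. The X to autosome ratio of EB day 7 replicate 1 was 0.798, against 0.749 to 0.757 in the others (ratio 0.837), and that of MEF replicate 4 was 0.641, against 0.747 to 0.778 (0.774). At day 2, Mir3072 stood at 166 FPKM in replicate 5 and at 0 in the others (1.000). Also at day 2, replicate 2 was apart in Tex19.1 (32.8 FPKM, ratio 0.881), Trh (47.9 FPKM, 0.774), Dnmt3a (68.4 FPKM, 0.744) and Nodal (55.2 FPKM, 0.719), and replicate 1 in Axin2 (2.32 FPKM, 0.751). At day 7, replicate 1 was apart in Nkx2-9 (54.2 FPKM, 0.767), Mcm2 (84.7 FPKM, 0.753) and Mgp (2.3 FPKM, 0.743), and replicate 3 in T (112 FPKM, 0.796) and Cdkn1a (26.7 FPKM, 0.751). Day 7 replicate 4 was apart in Dnmt3l (0.468 FPKM, 0.726) and Mcm7 (201 FPKM, 0.718), and replicate 5 in Fabp7 (34.5 FPKM, 0.831).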

How the results depend on the processing

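The tests without loci under 200 bases, with EpiSC values less the fibroblast share, without genes 10 times higher in MEF than at any day, with the mean per MEF culture for the X to autosome ratio and with the replicate block for gene lists were chosen only after the data were seen; all others were fixed before.

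Counts of called genes depended most on the pseudocount and on the minimum difference. With a pseudocount of 0.1 FPKM 3926 genes were called between days 2 and 0, 4449 and 3843 in EpiSC against days 2 and 7, and 796, 731, 2035, 1232 and 1341 in the 5 steps from day 2 to day 7. This follows from the construction, since a smaller pseudocount widens differences of genes near 0, where depth limits the precision most. With no minimum difference 7624 were called between days 2 and 0, 10305 between days 7 and 2, 9619 between days 7 and 0, 8648 and 7540 in EpiSC against days 2 and 7, 11170 and 11196 in MEF against days 7 and 0, and 3223, 1790, 4138, 2089 and 3902 in the steps, again by construction. A fit of the 2 groups only called 168 genes between days 4 and 3, against 335 in the fit of all groups, and the cause was not tested. All other alternatives left the counts within 1.5 times, including filters, rescaling, quantile normalization, the project as a covariate and each project alone.

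Leaving out 1 library at a time gave 244 to 446 called genes between days 3 and 2, with 446 without EB day 3 replicate 1, and the cause was not tested. No other count moved by more than 1.5 times. The X to autosome difference of day 7 from day 0 ranged from -0.439 to -0.499, with exact p from 0.0571 to 0.0952, and within project A it was -0.456 with an exact p of 0.1. That of MEF ranged from -0.463 to -0.523, with exact p up to 0.0714, and with the mean per MEF culture it was -0.486 with an exact p of 0.2. These were the smallest p-values that fewer libraries allow, so direction was kept and only the significance was lost.

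Lists passing depended on the treatment of correlation between genes. With an estimated correlation 1 list passed between days 7 and 2, 3 between days 7 and 0, 2 and 2 in EpiSC against days 2 and 7, and 2 and 1 in MEF against days 7 and 0. In the steps from day 2 to day 7 it was 0, 1, 2, 1 and 1. With fry 18 passed between days 2 and 0, 24 between days 7 and 2, 25 between days 7 and 0, 21 and 25 in EpiSC against days 2 and 7, 30 and 28 in MEF against days 7 and 0, and 4 between days 3 and 2. This follows from the question asked, since fry tests a list without reference to other genes. With a pseudocount of 0.1 FPKM 1 list passed between days 3 and 2 and 5 between days 7 and 6, and the cause was not tested. Of single lists, 92 lost their call with an estimated correlation, 119 gained and 2 lost it with fry, 10 gained and 13 lost it with the smaller pseudocount, and 2 gained and 1 lost it with the project as a covariate. No list changed direction.

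Of 288 named gene results, 268 were unchanged under every alternative. Of 5960 values under alternatives 31 were weaker, in 11 of the results, 6 were stronger and 5 were reversed. Those weaker were Sox2 (day 7 against day 0), Nodal (EpiSC against day 2), Cdk1 (EpiSC against day 7), Ddx3y (MEF against day 7), T and Mir3072 (day 3 against day 2), Nanog, T, Otx2 and Cox7b2 (day 4 against day 3) and T (day 7 against day 6). The loss came on leaving out 1 library for Nodal, Cdk1, Nanog at day 4 and T and Mir3072 at day 3. In a fit of 2 groups only it came for Nodal, Ddx3y, Mir3072 and, at day 4, Cox7b2, Otx2 and T. With project B only it came for Nodal, Cdk1, T and Mir3072 at day 3, Nanog at day 4 and T at day 7, and with project A only for Ddx3y. With quantile normalization it came for Sox2 and Nodal, with the project as a covariate for Nodal and with the smaller pseudocount for Nanog at day 4. The reversals all came from taking the fibroblast share away from EpiSC, which by construction lowers fibroblast genes and puts those below the share at 0. Against day 2 they were Bgn (-0.77), Col1a1 (-0.74), Col1a2 (-0.95) and Postn (-0.22), and against day 7 Bgn (-2.13). After this step 2667 genes were called against day 2 and 2633 against day 7, and without genes 10 times higher in MEF 2589 and 2304. The day nearest to EpiSC was day 4 under every alternative, these 2 included.

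The labels give the groups the same replicate numbers, but same-numbered libraries did not deviate together. Their mean correlation was 0.005 over 134 pairs, 15 of them over 0.1, and 8 of 34 libraries correlated best with their own number, so the numbers were not taken as a pairing. With the replicate block 2464 genes were called between days 2 and 0, 3805 between days 7 and 2 and 271 between days 3 and 2. Among lists 4 gained and 1 lost the call, and among named genes 1, T at day 3, lost it. By culture course the mean correlation was -0.001 over 46 pairs, 6 of them over 0.1, and the block called 3828 between days 7 and 2 and 318 between days 3 and 2, and Mir3072 at day 3 and Nanog at day 4 lost the call.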

Other observations

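The test of the Hox genes was written, and the genes of this part chosen, only after the results were seen.

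Noto and Foxj1 were high at day 5 and fell soon after. Noto stood at 81.1 ± 39.9 FPKM at day 5, 25.7 at day 6 and 0.675 at day 7, and Foxj1 at 82.9 ± 43.9 and 5.78 FPKM at days 5 and 6. Chrd (50.7 FPKM) was present at day 5, and Nog stood at 15.7, 15 and 6.53 FPKM at days 5, 6 and 7. Eomes stood at 50.6 ± 2.2 FPKM at day 4, Fgf8 at 113 and 126 FPKM at days 4 and 5, and Msgn1 at 23.1 ± 9.06 FPKM at day 5. Shh stood at 18.3, 82.6 and 81.3 FPKM at days 5, 6 and 7. Nkx6-1 rose from 17.8 to 61.8 and Nkx2-2 from 3.88 to 13.2 between days 6 and 7. Ntn1 stood at 39.9, 0.569, 22.2 and 65 ± 12.2 FPKM at days 0, 2, 6 and 7. Isl1, a gene of motor neurons, rose from 10.4 to 28.2 FPKM between days 6 and 7.

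Genes of retinoic acid were present at the end of the course although none was added per the labels. Aldh1a2, which makes it, stood at 62.3 ± 6.34 FPKM at day 6 and 27.5 at day 7, Cyp26a1, which breaks it down, at 42.2 FPKM at day 6, and the receptor gene Rarb at 14 and 15.6 FPKM at days 6 and 7. Trh stood at 2050 ± 59.9 FPKM at day 4. The keratin genes Krt8 (581 ± 162 FPKM) and Krt18 (380 FPKM) were high at day 6.

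Hox genes were on by day 7, with Hoxb2 at 59.5 FPKM and Hoxb9 at 19.7 FPKM. If Hox genes open in order along their clusters in this culture, genes with a higher paralog number would come on later. Over 24 Hox genes the rank correlation of paralog number and level-weighted mean day was 0.27 (permutation p = 0.206), so the order could not be shown. Pearson r had the other sign, -0.3. Hoxd13 stood at 1.81 FPKM at day 2 and 0 at day 7, so its mean day is not an onset. Without it the rank correlation was 0.44 (permutation p = 0.0371). As 1 gene decides the result, the order stays open. Of 12 Hox genes of paralog number 10 and above, 11 reached 1 FPKM in MEF, for example Hoxd13 (41.7 FPKM) and Hoxa10 (27 FPKM), and 0 did at days 3 to 7, which may put the course short of the posterior groups. Later days of the same culture, with rank correlation above 0 over the same genes, would test the hypothesis.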
